A study of Mus musculus with 4 samples.

How the data were processed

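ATAC-seq was performed on dental mesenchymal cells of incisors from wild-type C57BL/6 mice aged 4 weeks. Per the labels' protocols, cells were lysed and transposed, libraries were sequenced in paired ends on a NextSeq500, reads were aligned to mm10 with BWA-MEM, peaks were called with MACS2, and peaks were annotated and searched for motifs with HOMER. The submitters' processing notes also name STAR 2.6.1d and Partek, without their roles. Whether reads were shifted for the transposase offset, whether duplicate or mitochondrial reads were removed, and on which libraries regions were called is not given in the sources used here. Unremoved duplicates would raise the counts of some regions, and a region set called partly on other libraries would hold regions without reads here; 7101 regions (5.84%) had 0 reads.

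The authors deposited a table of expected counts per region, in which 10 of 16382 values were not whole; as held here it covers chromosomes 10 and 11 and part of 12. The authors also deposited a table of 121574 regions with values in CPM, each 1 read added and divided by a library size that the file does not give. Values were whole multiples of 0.0484, the value of 1 read, for 99.9% of regions (tolerance 0.01 read; 84 exceptions), so reads were recovered as the multiple minus 1. The recovered reads equalled the deposited expected counts within 0.02 in all 16382 regions of the shorter table (largest difference 0.00047). The step implies a divisor of 20662737, of which reads in regions were 11.1%. The table also holds 1 value column for which no sample was given, and it was not used. Coordinates are those of the authors, written from 1; 25750 regions (21.2%) abut the region before them, and none lies on the mitochondrial genome or an unplaced sequence.

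The 4 samples are lanes 1 to 4 and appear in both tables under 1 shared name. The design fixed before the data were examined assumed a value per lane. Agreement between lanes, intervals over lanes, other library scalings and leaving out a lane could therefore not be run, and no test compares conditions. With 1 library, percentiles among random lists describe this library and not a population of animals.

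Regions were classified by their midpoint on the GENCODE vM21 basic annotation of GRCm38 (mm10), first as promoter (within 1 kb of a protein-coding TSS) and then by exon part, intron, noncoding gene or intergenic sequence. Shares were compared with 97126 random genome positions. Each region was assigned to the protein-coding gene with the nearest TSS; this rule gives genes beside long gaps many regions and need not name the gene a region regulates. Promoter reads of a gene are those of regions overlapping 1 kb either side of any of its TSSs, whichever gene the region was assigned to; reads elsewhere are those of its assigned regions whose midpoint is not in the promoter class, so the 2 need not add up to its reads. A gene's level was log2(CPM + 1), with CPM here relative to all reads in regions, summed over its regions. A gene without a region has no value and was left out, which is not a measured absence.

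A total of 25 gene lists, covering dental and skeletal lineages, signalling pathways and other cell types, were fixed before the data were examined. Some lists share members: 8 of 17 odontoblast, 8 of 12 osteoblast, 4 of 15 incisor niche, 3 of 16 mesenchymal progenitor and 2 of 12 hedgehog genes are in another list. The median level of each was placed among 10000 random lists of the same size drawn from the 16816 genes with a region (seed 11). A list was called above or below when the share of random lists as extreme, on both sides, was at most 0.05 after Benjamini-Hochberg adjustment over the lists. On 200 simulated lists of 15 of these genes, 4.5% of unchanged lists fell outside the central 95% of random lists, 53.0% of those raised by 1 log2 unit did, and 95.0% of those raised by 2 did. Named genes followed a fixed rule: the 10 largest regions and genes, the 3 most and the 1 least accessible member of each list with a region, and Runx2, Gli1 and the IGF genes in any case; 4 genes that the rule takes are not reported here. Homeobox families, trunk and limb factors, collagens and other families, and 20 motifs were added after the tables were opened but before their values were seen. The windows around Dlx5, Dlx6 and HoxA, En1, Pax1, Tbx5, the promoter groups of Runx2, the upstream Msx regions and the features after removal of mitochondrial matches were named after their values were seen.

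Motifs were counted on both strands as exact matches to a consensus, at most once a region, in at most 15000 randomly drawn regions a set and in equally long flanks 2 kb away that overlap no region. Ratios add 0.5 to both counts, which was put in after the first motif results and left the enriched motifs away from promoters at 5 and lowered those in regions under 10 reads by 1. Up to 30 shuffled versions with as many CG pairs served as the comparison, since regions had a higher GC content than flanks (49.4% against 44.9% away from promoters). A motif was counted as enriched above all shuffles and above 1.2 times their median. Regions were matched to the mitochondrial genome and to the chromosomes with BLAST 2.17.0, at 90% identity as planned and at 75% after the first result was seen. Both the motif count and the match were tested on simulated sequences. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, samtools 1.23.1 and matplotlib 3.10.9. Alternatives covered low-count filters, pseudocounts, the summary over a gene, region length, region class and matched random lists.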

Results

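Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in dental mesenchymal cells of incisors from wild-type C57BL/6 mice aged 4 weeks. The mouse incisor grows throughout life, and its mesenchyme, the tissue inside the tooth, renews the odontoblasts that lay down dentin and the fibroblast-like cells of the pulp. All 4 deposited samples belonged to 1 group, and their titles differed by lane number alone. The values stood under 1 name shared by the 4 lanes, so 1 library was described, with no replicate error and no contrast between conditions. It held 121574 open regions with 2297892 reads. A region had a median of 7 reads (quartiles 3 and 16), and the largest had 10649. Regions covered 39.0 Mb, with a median width of 261 bp. Intervals given with read counts are exact 95% Poisson intervals, which cover counting error alone and take each count as independent. Whether a count stands for a read or a fragment is not given in the sources used here. If mates or duplicates were counted separately, these intervals and the binomial interval of the share of reads are too narrow. The median region's interval ran from 2.81 to 14.4 reads, whereas that of a region with 100 reads ran from 81.4 to 121.6.

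Promoters held most of the signal. Windows of 1 kb either side of an annotated protein-coding transcription start site (TSS) made up 2.02% of the genome, held 20.1% of regions and took 50.5% of the reads in regions (exact 95% binomial interval 50.5% to 50.6%). Introns held 37.0% of regions and 21.4% of reads, and intergenic sequence 33.9% of regions and 21.2% of reads. Of the 1000 regions with the most reads, 90.3% were promoters. A region lay at a promoter of 14102 of 21827 protein-coding genes (64.6%), and 16816 genes had at least 1 region nearest to their TSS. These genes had a median of 4 regions and 85 reads. Separate medians were 48 reads in regions at a promoter of the gene, which can be nearest to another gene, and 22 in its regions elsewhere.

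**Figure D1:**
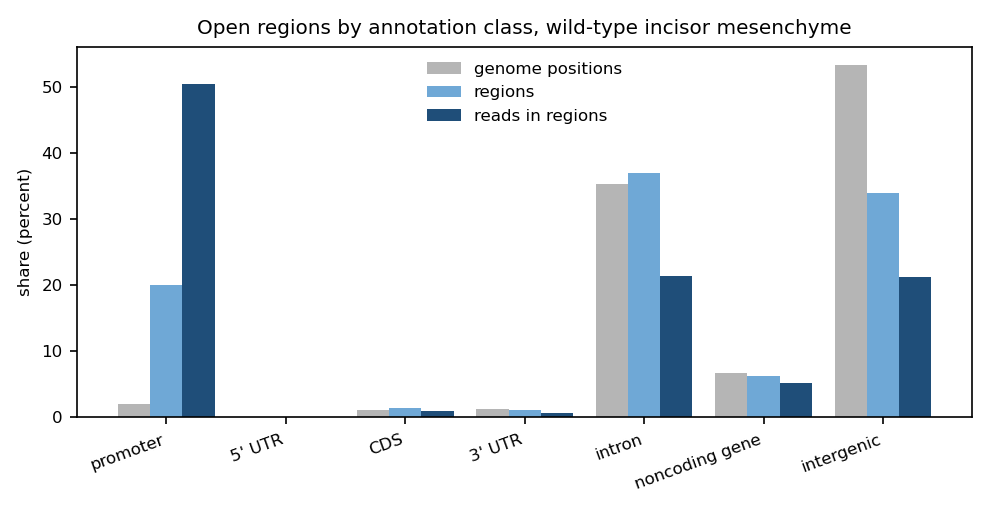
Share in percent of genome positions (grey), open regions (light blue) and reads in regions (dark blue) by annotation class of the midpoint, for the single library. Promoters hold 2.02% of positions, 20.1% of regions and 50.5% of reads, while intergenic sequence holds 53.4% of positions and 21.2% of reads.

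Transcription factors that mark dental mesenchyme lay in densely accessible surroundings. All 21 listed genes had a region, 19 had reads above the median gene, and their median was 295 reads over 16 regions. Msx2, a homeobox factor of the early tooth, had 1061 reads (998 to 1127) over 64 regions. Msx1, without which teeth do not form, had 547 (502 to 595) over 24 regions. The least accessible member, Foxd1, had 61 reads (46.7 to 78.4). On the log2(CPM + 1) scale the list's median was 7.02, against 5.25 for the median of 10000 random lists of the same size, and it lay at the 100th percentile of them. The list medians were 86 promoter reads and 206 reads elsewhere. Scored on promoter regions alone the difference was 0.40, per kilobase of region it was 0.05, and with the largest region of each gene it was 0.94, none of which passed the adjusted threshold. Against lists matched on span and promoter CpG density it was 1.0, which passed. On regions away from promoters alone it was 3.10, a setting in which 13 of the 25 lists passed, among them the endothelial and dental epithelium lists.

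The largest regions of the Msx genes illustrate this layout. At Msx2 on chromosome 13 (mm10 throughout), the promoter region from 53472568 to 53473151 had 133 reads (111 to 158), and a region from 53531745 to 53532570, in a noncoding gene 59.1 kb upstream, had 103 (84.1 to 125). At Msx1 on chromosome 5, the promoter region from 37824144 to 37824908 had 150 reads (127 to 176). A region from 37895545 to 37896411, also in a noncoding gene and 71.4 kb upstream, had 72 (56.3 to 90.7).

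Odontoblast genes also lay above random lists (difference 1.44, 99.94th percentile), and osteoblast genes, which share 8 of their 12 members with other lists, did not (0.27, 67.5th percentile). Klf4, a zinc finger factor, had 997 reads (936 to 1061), Bmp2, a growth factor ligand, had 712 (661 to 766) and Col1a2, a chain of type I collagen, had 565 (519 to 614). Dspp, which encodes the main noncollagenous protein of dentin, was the least accessible odontoblast gene with a region. It had 44 reads over 6 regions, with 18 of the reads at its promoter. The sequence nearest to the TSSs spanned 44.4 kb for Dspp, against 695 kb for Klf4, 804 kb for Bmp2 and 257 kb for Col1a2. This span enters the contrast between them. Among osteoblast genes, Col1a1 had 367 reads (330 to 407), Sp7, a factor needed for bone formation, had 282 (250 to 317), and Sost, an osteocyte product, had 15 (8.40 to 24.7). The odontoblast list lost its call with the largest region of each gene (0.56), per kilobase of region (0.29) and on promoter regions alone, where its difference was -0.71. Chondrocyte genes (86.9th percentile), dental follicle and periodontal genes (78.9th) and mesenchymal progenitor genes (89.5th) stayed within the range of random lists. With the mean in place of the median the progenitor list was above them (1.01), and on regions away from promoters alone the chondrocyte (2.05) and dental follicle (2.21) lists were. In these, Sox9 had 846 reads (790 to 905), Sox5 had 436 and Sox6 had 430, against 1 read at the hypertrophic cartilage collagen Col10a1. The sequence nearest to their TSSs spanned 1250, 1072 and 765 kb for the Sox genes and 60.5 kb for Col10a1, which enters this contrast. Ptn had 568 reads, Pth1r 296 and Mkx 196, with 19 at the tendon gene Tnmd. Nt5e had 568 and Twist2 438, with 31 at Eng.

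**Figure D2:**
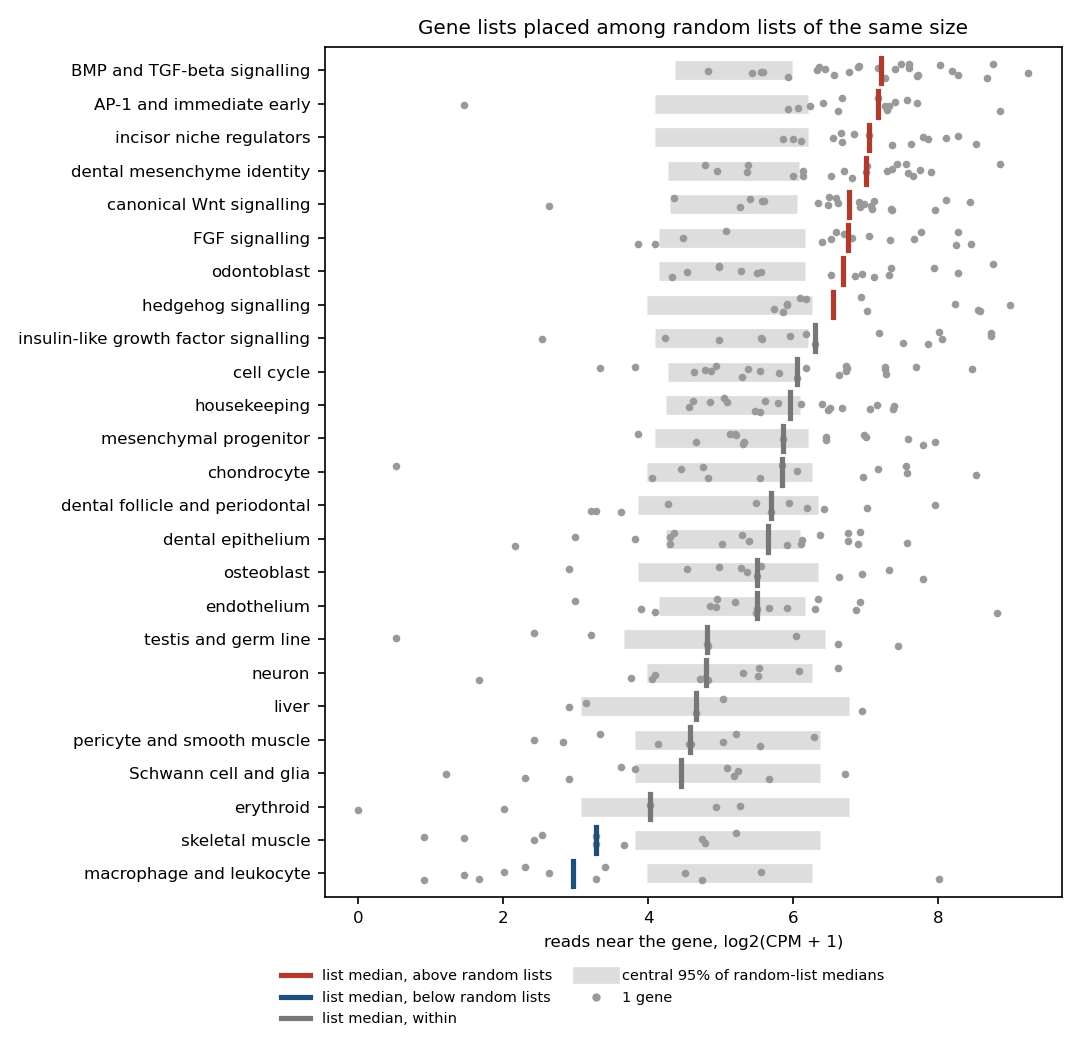
Accessibility of 25 gene lists in the single library, as log2(CPM + 1) of the reads in all regions nearest to a gene, with 1 grey point per gene. Coloured bars are list medians (red above, blue below, grey within random lists), and light grey bands hold the central 95% of medians of 10000 random lists of the same size. The 8 red lists have medians from 6.56 to 7.22, and the 2 blue lists have medians of 3.28 and 2.96.

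Genes of 4 developmental signalling pathways lay above random lists, the BMP and TGF-beta list furthest (difference 1.98, 100th percentile, 25 of 26 genes above the median gene). Its largest members were the inhibitory Smads, Smad7 with 1399 reads (1327 to 1474) and Smad6 with 1000 (939 to 1064), and the ligand Bmp7 with 939 (880 to 1001), while the antagonist Fst had 63 (48.4 to 80.6). Canonical Wnt genes followed (1.52, 99.99th percentile) with Tcf7l2 at 802 reads (747 to 859), the beta-catenin gene Ctnnb1 at 633 (585 to 684), Tcf7l1 at 572 (526 to 621) and the secreted antagonist Notum at 12 (6.20 to 21.0). FGF genes (1.51, 99.97th percentile) were led by the receptor Fgfr2 with 804 reads (749 to 862), the feedback inhibitor Spry2 with 712 (661 to 766) and Fgfr1 with 695 (644 to 749), and Fgf7 had 31 (21.1 to 44.0). In the hedgehog list (1.31, 99.45th percentile) all 12 genes exceeded the median gene. Gli3 had 1175 reads (1109 to 1244), Gli2 877 (820 to 937), the receptor Ptch1 864 (807 to 924) and the pathway inhibitor Sufu 120 (99.5 to 143). The sequence nearest to the TSSs, which enters the sums of all 4 lists, spanned 691 kb for Gli3 and 53.0 kb for Sufu. At Tcf7l2 and Notum it was 562 and 12.5 kb. At Fgfr2 and Fgf7 it was 464 and 140 kb, and at Smad7 and Fst 341 and 215 kb. Per kilobase of region, the BMP and TGF-beta, Wnt and FGF lists fell slightly below random lists (-0.039, -0.16 and -0.26), and no pathway list passed the threshold, nor did any on promoter regions alone (0.80, -0.27 and 0.50, and 0.90 for hedgehog). Against random lists matched on both the span of sequence nearest to each gene and promoter CpG density, the hedgehog, Wnt and FGF lists no longer passed it (0.37, 0.62 and 0.36). The hedgehog and FGF lists lost their calls matched on span alone (0.73 and 0.81), the hedgehog list also matched on CpG density alone (0.93) or with regions under 10 reads left out (0.93), and the Wnt and FGF lists with the largest region of each gene (0.64 and 0.57).

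AP-1 and immediate early genes, which respond rapidly to stimulation and to tissue handling, had a difference of 1.92 (100th percentile). Jun had 1067 reads (1004 to 1133), of which 566 were at its promoter, Fos had 478 (436 to 523) and Fosl2 had 435 (395 to 478), whereas Fosl1 had 4 (1.09 to 10.2). Per kilobase of region (0.50) and on promoter regions alone (0.11) the list did not pass the threshold. Regulators known from the incisor stem cell niche, a list that was assembled with knowledge of this field, had a difference of 1.81 (100th percentile); 4 of its 15 members are in other lists, and all 15 exceeded the median gene. Its largest members besides Sox9 were the Wnt receptor Fzd1 with 712 reads (661 to 766) and the chromatin remodeller Arid1b with 637 (588 to 688). It was the 1 list above random lists on promoter regions alone (1.32), and it did not pass per kilobase of region (0.75) or against lists matched on both span and CpG density (0.54).

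Runx2, the master factor of the osteoblast lineage, had 507 reads (464 to 553) over 48 regions, more than 96.6% of genes. Its TSSs on chromosome 17 fell into a distal group (44814226 to 44814797) with 24 reads (15.4 to 35.7) and a proximal group (44735634 to 44736648) with 59 (44.9 to 76.1). The Runx2 region with the most reads was intronic, from 44505554 to 44506069, with 61 reads (46.7 to 78.4). Gli1, a hedgehog target that marks stem cells of the incisor mesenchyme, had 132 reads (110 to 157) over 5 regions, at the 65.4th percentile of genes. Of these, 64 (49.3 to 81.7) lay in an intronic region from 127338962 to 127339486 on chromosome 10, and 28 (18.6 to 40.5) at the promoter. The sequence nearest to the TSSs spanned 623 kb for Runx2 and 15.3 kb for Gli1, and it enters these sums and percentiles.

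Insulin-like growth factor (IGF) signalling genes lay at the 98.4th percentile of random lists, a difference of 1.05 that did not pass the adjusted threshold. It passed on regions away from promoters alone (2.52), with regions under 10 reads left out (1.27), with the mean in place of the median (1.46) and with genes without a region included (1.74). It lay near or below random lists per kilobase of region (-0.20), on promoter regions alone (-0.11), with the largest region of each gene (0.11) and against lists matched on span and CpG density (0.12). Among the genes named as IGF binding proteins, Igfbp7 had 981 reads (921 to 1044) over 64 regions and Igfbp3 had 532 (488 to 579) over 47. Igfbp4 had 140, Igfbp5 107, Igfbp2 70, Igfbp1 27 and Igfbp6 11. The wide gaps around Igfbp7 and Igfbp3, with 1856 and 733 kb nearest to their TSSs, enter these sums. The Igfbp3 promoter region, chromosome 11 from 7213526 to 7214119, had 58 reads (44.0 to 75.0). The receptor gene Igf1r had 594 reads (547 to 644) and Igf2r 179 (154 to 207), and the ligand genes Igf1 and Igf2 had 164 (140 to 191) and 106 (86.8 to 128). Among the intracellular components, Irs2 had 976 reads (916 to 1039) and Pik3r1 610 (563 to 660). The sequence nearest to their TSSs spanned 520 and 968 kb, and it enters these 2 sums as well.

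**Figure D3:**
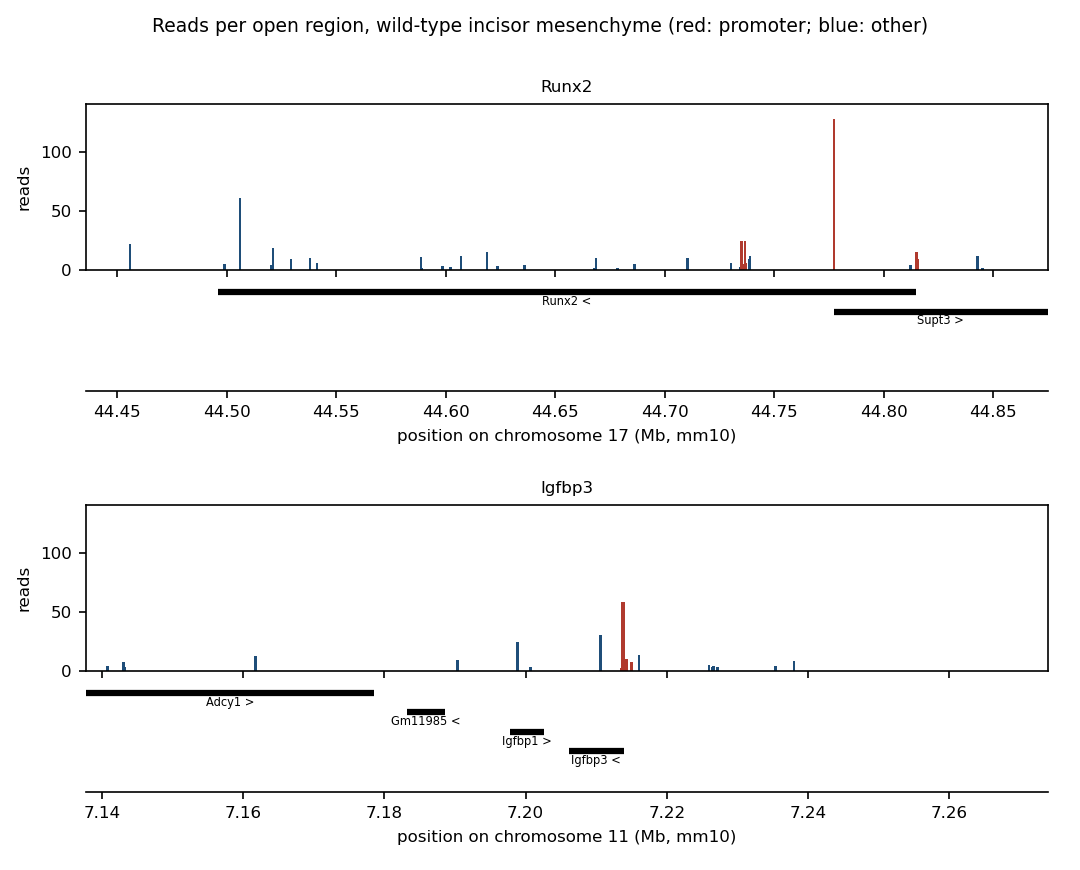
Reads per open region (y axis, counts) along chromosome 17 around Runx2 and chromosome 11 around Igfbp3 (x axis, Mb, mm10) in the single library; red bars are regions whose midpoint lies within 1 kb of a TSS, blue bars are other regions, and black lines are genes with their strand as an arrow. The tallest bar of the Runx2 window, 128 reads, stands at the start of Supt3, and the tallest of the Igfbp3 window, 58 reads, at the Igfbp3 promoter.

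Macrophage and leukocyte genes lay below random lists (difference -2.29, percentile 0.05), with no region at 6 of 18 genes and a promoter region at 3, and so did skeletal muscle genes (-1.96, percentile 0.43). The calls held in 7 and 8 of 14 settings: the differences shrank and the calls ended against lists matched on promoter CpG density (-1.06 and -1.18), per kilobase of region (-0.82 and -0.84), away from promoters alone (-0.87 and -0.12) and, for the macrophage list, with regions under 10 reads left out (-0.81). The calls also ended on promoter regions alone (-2.90 and -1.53) and with genes without a region included (-2.72 and -1.62), where the differences were of similar size. Ptprc, the pan-leukocyte gene, stood out with 591 reads (544 to 641), none of them at its promoter and the largest region 164.0 kb from its TSS. Laptm5 had 106 reads, Adgre1 59 and Tyrobp 2. Ttn had 83 reads, Myf5 61, Tnnt3 59 and Acta1 2. The remaining other-tissue lists stayed within random lists when all regions were scored. The endothelial list lay at percentile 69.2: Cdh5 had 1032 reads (970 to 1097) and 13 promoter reads, Flt1 had 278, Emcn 267 and Tie1 16. On promoter regions alone the endothelial list lay below random lists (-2.00), and on regions away from promoters alone it lay above them (1.91). The dental epithelium list lay at percentile 81.7, with 434 reads at Sox2, 276 at Mmp20, 273 at Cldn10 and 8 at Amelx, the amelogenin gene, and it too lay above on regions away from promoters alone (1.71). Pericyte and smooth muscle genes (percentile 16; Kcnj8 178, Myh11 105, Acta2 83, Cnn1 10 reads), Schwann cell and glial genes (12.3; Mbp 240, Ngfr 85, Gfra3 3) and neuronal genes (23.0; Map2 223, Snap25 154, Elavl4 104, Elavl3 5) also lay within. So did erythroid genes (11.4, from 5 of 10 genes; Klf1 68, Epor 35, Slc4a1 0), liver genes (26.9, from 5 of 12 genes; Apob 282, Ttr 73, Apoa1 56, Fga 15) and germ line genes (28.2, from 8 of 12 genes; Tnp1 401, Nobox 223, Dazl 149, Prm1 1). With genes without a region included, the liver list was called below (-4.52), and the erythroid list, at -4.54, was not. Cell cycle genes lay at percentile 97.1 (Ccne1 817, Cdkn1b 477, Ccnd1 356, Ccnb2 21 reads) and housekeeping genes at 94.3 (Eef1a1 380, Ywhaz 326, Tbp 52), and neither passed the threshold. Against lists matched on span both did (0.96 and 1.16), as they did with the mean in place of the median (0.94 and 0.95); housekeeping genes also passed with the largest region of each gene (1.19) and cell cycle genes with genes without a region included (1.38), and housekeeping genes formed the 1 list above random lists per kilobase of region (1.13).

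Homeobox families split sharply; they were measured in addition to the fixed lists. The 6 Dlx genes, which pattern the jaw, all had a promoter region, with 1798 reads in all and a median of 306; 5 of them are also in the dental mesenchyme list. The 39 Hox genes, which pattern the trunk and limbs, had 159 reads in all and a median of 0 with genes without a region counted as 0, and a region was nearest to 19 of them (48.7%, exact 95% binomial interval 32.4% to 65.2%) and at the promoter of 11. The interval takes the genes as independent, although they lie in clusters. In a window of 119 kb around Dlx5 and Dlx6 on chromosome 6, 24 regions held 607 reads (560 to 657), whereas 5 regions with 28 reads (18.6 to 40.5) lay in the 125 kb window of the HoxA cluster. Of 21 trunk and limb factors, 13 were Hox genes, and the low median of that list, 8 reads, rested on them. Its 8 other members all had a region, with reads from 8 at Tbx5 to 214 at Pax1 and 429 at En1.

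**Figure D4:**
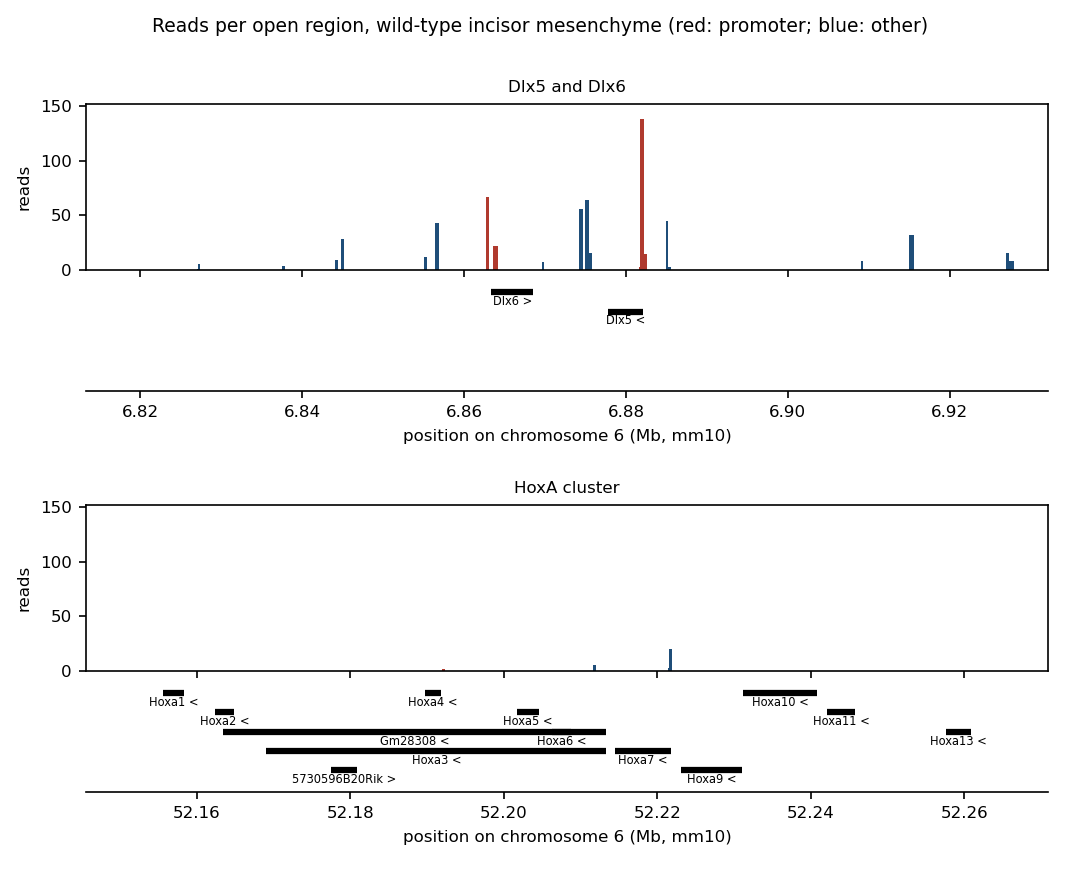
Reads per open region (y axis, counts, same scale in both panels) along chromosome 6 around Dlx5 and Dlx6 and across the HoxA cluster (x axis, Mb, mm10) in the single library; red bars are promoter regions, blue bars other regions, and black lines genes with their strand as an arrow. The Dlx window reaches 138 reads in a region, and the HoxA window reaches 20.

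Consensus binding motifs were counted in 15000 regions with at least 10 reads away from promoters, against flanking sequence 2 kb away, beside shuffled versions of each consensus. The 95% intervals of the ratios of regions to flanks take the 2 as independent samples, although each flank is paired with a region. They also take neighbouring regions as independent. Of 20 motifs, 5 exceeded every shuffled version. The CTCF motif, bound by the insulator protein, was in 9.77% of regions and 0.52% of flanks, a ratio of 18.7 (95% interval 14.9 to 23.4) against at most 4.6 for its shuffles. The homeodomain core bound by Dlx, Msx, Alx and Lhx factors was in 20.3% of regions and 10.2% of flanks. Its ratio was 1.99 (1.88 to 2.11), against at most 1.26 for its 13 shuffles. Exceeding 13 shuffles is a weaker test than exceeding the 30 of the CTCF motif. The MEF2 (1.96, 1.54 to 2.48), forkhead (1.65, 1.52 to 1.80) and TEAD (1.23, 1.18 to 1.29) motifs followed. The RUNX core was in 32.5% of regions and 27.5% of flanks (1.18, 1.14 to 1.22), and 2 of its 19 shuffles reached as high. The AP-1 motif (1.28, 1.19 to 1.38) was reached by 1 of 30, but in regions under 10 reads it exceeded every shuffle (1.61, 1.46 to 1.79), as did the PU.1 motif there (1.60). At promoters the CRE motif of Atf and Creb factors (11.3, 8.37 to 15.3) and the nuclear factor Y motif (1.53, 1.46 to 1.60) exceeded all their shuffles, as did the PU.1 motif (1.15) and the MEF2 motif, whose own ratio was below 1 (0.417). The homeodomain core was in 3.54% of promoter regions and 16.6% of their flanks, a ratio of 0.214. Its shuffles had a median of 0.146, and 2 of 13 reached as high, so the low share is not a depletion relative to them. Promoter regions had a GC content of 63.7%, against 44.8% in flanks.

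**Figure D5:**
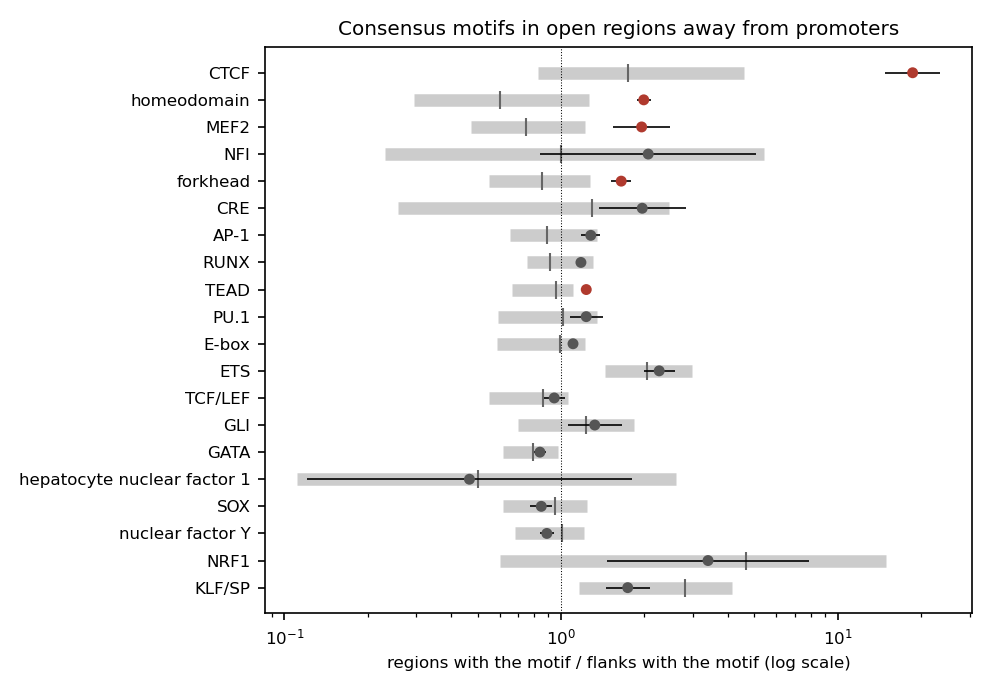
Ratio of open regions with a motif to flanks with it (x axis, log scale) for 20 consensus motifs away from promoters in the single library. Points are ratios with 95% intervals, grey bars span the ratios of the shuffled consensuses with their median as a tick, and red points mark the 5 motifs above every shuffle, led by CTCF at 18.7.

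The 10 regions with the most reads were mostly not gene promoters. The largest, chromosome 4 from 80004732 to 80005200, had 10649 reads (10448 to 10853) in a noncoding gene 829264 bp from the TSS of Tyrp1, the nearest gene. Next came a region on chromosome 13 from 9011703 to 9012168, in a noncoding gene near Gtpbp4, with 4532 reads (4401 to 4666). The others were nearest to Fbxo33 (3863 reads), Tex47 (3824), Tbx20 (3279), 4931406C07Rik (2871), Slc25a54 (2837), Ghitm (2150), Smyd3 (2141) and Gdf6 (1935), and of the 10 the Ghitm region alone was a promoter. Over at least 50% of their length, 8 of the 10 matched the mitochondrial genome at 75% identity or more. The same 10 genes had the most reads by gene, from 10675 at Tyrp1 to 2545 at Gdf6, since these single regions dominate their sums. With the 19 regions that matched the mitochondrial genome left out, Gtpbp4 (4673 reads) and Ghitm (2730) were followed by Sox4 (1658), the mesenchymal cadherin gene Cdh11 (1632), Klhl29 (1563), Mex3c (1532), Zfat (1453), Myc (1448), Smad7 (1399) and Efnb2 (1378). The sequence nearest to the TSSs of these 10 genes spanned from 70.5 kb (Gtpbp4) to 2343 kb (Cdh11), and it enters their sums. With the same regions left out, the largest regions were, after those at Gtpbp4 and Ghitm, the promoters of Ppp2r3d (1330 reads), Ripk2 (1084), Sp4 (954), Zfp78 (795), Zfp91 (775), Ube2d3 (770), Gsk3b (756) and Nr1d2 (755).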

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

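Planned settings were a filter on regions under 10 reads, pseudocounts of 0.1 and 5, the largest region of a gene, the mean of log values and reads per kilobase of region; the 8 other settings of the lists and those of motif depth, merged regions and mitochondrial matches were chosen after seeing the data. The count of 8 lists above random lists stayed within 1.5 times under both pseudocounts, the filter, the mean, the 100 kb limit, the inclusion of genes without a region, matching on span or on CpG density and removal of mitochondrial matches (7 to 12). It was 5 with the largest region, 1 per kilobase of region (housekeeping, not among the 8), 1 on promoter regions alone (incisor niche regulators), 13 away from promoters alone and 4 with lists matched on span and CpG density. The count of 2 lists below was 1 with the filter (skeletal muscle), on promoters alone (endothelium) and with genes without a region included (liver), although the macrophage difference of -2.29 was -2.90 and -2.72 in the last 2, and 0 per kilobase of region, away from promoters alone, and with lists matched on CpG density with or without span. The dental mesenchyme difference of 1.77 held in 11 of 14 settings and lost its call with the largest region (0.94), per kilobase (0.049) and on promoters alone (0.40). Per kilobase of region the Wnt (-0.16), BMP and TGF-beta (-0.039) and FGF (-0.26) lists turned below random lists, and on promoters alone the odontoblast (-0.71), Wnt (-0.27) and endothelial (-2.00) lists did, the last past the threshold. Lists within random lists before and after also turned on promoters alone: mesenchymal progenitor (-0.43), osteoblast (-1.23), dental follicle (-0.61), chondrocyte (-0.88), IGF (-0.11) and dental epithelium (-0.95), all of which were also below per kilobase of region (-0.19, -0.36, -0.55, -0.50, -0.20 and -0.28), as was endothelium (-0.34). The largest region put mesenchymal progenitor (-0.059), osteoblast (-0.73), dental follicle (-0.18), chondrocyte (-0.36), dental epithelium (-0.44) and endothelium (-0.41) below without a call. The filter did so for osteoblast (-0.14), dental follicle (-0.031) and endothelium (-0.29). Germ line genes turned the other way on promoters alone (0.73), also without a call. Scoring promoters alone or the largest region uses fewer regions by construction; otherwise the cause was not tested. Of the 10 largest regions and of the 10 largest genes, 2 each remained once regions matching the mitochondrial genome were left out; merging abutting regions kept all 10 regions. Leaving out mitochondrial and unplaced features removed nothing, so it says nothing about stability. The motif count of 5 was 7 in regions under 10 reads, with AP-1 and PU.1 gained, and 5 in regions of 30 reads or more. Not run, since the values are not split by lane and no comparison columns were used: other library scalings, leaving out each lane, agreement between lanes and thresholds of a comparison table. Depth limits single regions, as the median region of 7 reads has a relative counting error of 37.8%.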

Other observations

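Other gene families differed widely. All 44 collagen genes had a region, with medians of 122 reads in all and 27.5 at promoters, and 93.9% of 82 ribosomal protein genes had one, with a median of 73.5 reads at promoters and 6.5 elsewhere. A region was nearest to 8.91% of 1133 olfactory receptor genes (exact 95% binomial interval 7.32% to 10.7%), 12.5% of 328 vomeronasal receptor genes, 16.1% of 56 clustered protocadherin genes and 61.2% of 49 keratin genes. Housekeeping genes had their reads at promoters (list medians 117.5 there and 6 elsewhere), whereas dental mesenchyme genes had 86 and 206. The Igfbp3 surroundings held the RUNX core in 14 of 47 regions and those of Runx2 in 13 of 48, beside 0 of 5 at Gli1. Among sampled regions of the whole library it was in 20.9% at promoters and, away from promoters, in 32.5% of those with at least 10 reads and 19.5% of those with fewer; the loci, which mix these kinds, were not tested against them.

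In the weighing that follows, the tests of Hox genes and the mitochondrial match at 75% identity were chosen after the results were seen, and with 1 group no biological explanation was tested. The 10 largest regions outside promoters held 1309 to 10649 reads. Full-length copies elsewhere in the chromosomes are argued against as the main source, since of the 8 regions without a 90% match to the mitochondrial genome, 0 had 10 or more places at 90% identity over 80% of their length. At 90% identity 2 of the 10 regions matched the mitochondrial genome, between the bounds set in advance, so that test left mitochondrial reads open. At 75% identity 9 of 10 matched over at least 50% of their length, against 0 of the 28905 regions outside promoters with 7 to 16 reads, and the 19 matching regions held 1.68% of reads. Reads of mitochondrial DNA placed on older nuclear copies are therefore a candidate explanation for those 9; for the region near Gtpbp4, with 1 full-length place but 3767 or 7969 matches of at least 60 bp in the chromosomes, by the word length and alignment mode of the search, partial repeats stay open.

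Dental mesenchyme identity genes lay above other genes. Such genes often sit in wide gaps and have CpG-rich promoters, and either could raise the reads assigned to them. Matching took away part of the difference of 1.77, which was 1.2 with span of sequence nearest to each gene matched, 1.5 with promoter CpG density matched and 1.0 with both. Neither accounted for all of it, since the list lay at the 99.98th percentile of lists matched on span and at the 100th of lists matched on CpG density. These genes had a median of 16 regions, against 4 for all genes with a region. The difference was 0.049 per kilobase of region and 0.94 with the largest region of each gene. Reads per kilobase cancel both the number and the width of regions, so that value cannot tell them apart. It also depends on region class, with 104.8 reads per kilobase at promoters, 38.6 in introns and 40.9 in intergenic sequence. Whether the larger number of regions is particular to this tissue cannot be tested in 1 library without a second tissue.

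Hox genes had few reads beside many at dental factors, a pattern that may mirror the cranial origin of the tissue, which was not tested. Low CpG density is argued against, as the Hox median of 0 promoter reads lay at percentile 0 of 10000 sets of genes matched on promoter CpG density, whose median was 57 reads. Narrow spacing may explain part, since genes matched on span had a median of 20 reads and the Hox median lay at the 0.89th percentile. Both kinds of matched sets were drawn gene by gene, whereas Hox genes are neighbours in clusters. The percentiles take neighbours as independent and so overstate the evidence by an amount that was not measured. Unplaceable sequence is argued against, because 99.0% of the 36-base windows in Hox promoters occur once in the chromosomes, against 98.9% at dental mesenchyme promoters. How the region set was called and filtered stays open.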
